A study of Mus musculus with 20 samples.

How the data were processed

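Mouse CD4 T cells of the TH17 type, which make interleukin-17, were profiled by RNA-seq in 12 libraries. They form 6 groups with 2 replicates each. Per the labels, TH17 cells were sorted as GFP-positive cells from suspensions of the central nervous system (CNS) and of the ileum. TH17(β) cells, cultured with TGF-β1 and IL-6, carried either a c-Rel overexpression construct (Ad-c-Rel) or its control (Ad-control). Pathogenic TH17 cells, cultured with IL-6, IL-1β and IL-23, came from miR-21 knockout or control mice. The 8 ATAC-seq samples of the series were not analysed here. Per the labels' protocols, the sorted cells were prepared with a low-input SMART-Seq v4 kit and the miR-21 cultures with a stranded total RNA kit. The kit of the Ad-control and Ad-c-Rel libraries is not clearly given in the sources used here.

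Each deposited file holds raw counts per gene symbol, made by the authors. The submitters' processing notes name CASAVA 1.4, Trim Galore 0.4.4, Bowtie2, SAMtools, HOMER, TopHat2 2.1.0, HTSeq 0.11.0, DESeq2 and the mm10 genome build, with no role or order. The annotation and the strand setting of the counting are not given in the sources used here. Each table has 24862 gene rows, of which 24326 symbols were found in the Ensembl name table. Summary lines that name no gene stayed out of library sizes and tests. They held 14.7% to 26.1% of each table's total. The line for reads without an annotated gene held 9.65% to 24.1%. The line for reads with several alignments held 0 in the 4 miR-21 libraries and 2.25% to 3.52% in the others, so reads of near-identical genes can be treated differently in those libraries. Ambiguous reads were 1.89% to 3.04%. They affect overlapping genes. Eno1 was listed at 0 to 8 counts per library beside an overlapping entry, Eno1b, and is not interpreted. Mir21a is the short precursor gene next to Vmp1, so its counts do not measure the mature microRNA. The tables hold none of the transcripts encoded in the mitochondrial genome that were on the mitochondrial list.

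Gene counts summed to 1.68e+07 and 1.92e+07 in the CNS libraries, 1.63e+07 and 1.70e+07 in the ileum libraries, 1.54e+07 and 1.99e+07 for Ad-control, 1.76e+07 and 1.64e+07 for Ad-c-Rel, 3.48e+07 and 3.28e+07 for the miR-21 knockout and 3.64e+07 and 3.67e+07 for its control. Genes with any count numbered 14224 and 11545 in CNS replicates 1 and 2, and 13927 and 10771 in ileum replicates 1 and 2. Replicate 2 was thus the deeper library of each tissue but held fewer genes. Replicates correlated at r = 0.928 in CNS and 0.915 in ileum, against 0.989 to 0.997 in the other groups. Replicates of a group differed by more than sampling noise (chi-square per degree of freedom 4.60 to 67.8, over genes with at least 10 counts in the pair), so no pair was counted as 1 sample. The labels do not say whether replicates came from separate animals or cultures. The p-values of single genes therefore measure the spread between these samples, which may be technical. Intervals (95%, exact binomial) and floors (3 counts over the 2 libraries of a group) cover counting error only, since PCR copies were not marked by molecular identifiers.

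Each comparison was fitted on its own 4 libraries with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM scaling, the quasi-likelihood F test (two-sided) and Benjamini-Hochberg adjustment with a threshold of 0.05. Log2 fold changes are given with standard errors (SE), and levels as TMM-scaled values on the counts-per-million scale (CPM, mean ± SD, n = 2). Each SE is the absolute log2 fold change over the square root of the F statistic. It therefore restates the F test and was not estimated separately by the model. Groups of 2 leave 2 residual degrees of freedom before the spread is moderated across genes. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation and with fry. At the preset correlation camera compares genes with genes, so its p-values do not measure the spread between libraries. At an estimated correlation it rests on the 2 residual degrees of freedom, so large p-values there can come from the small groups alone. In CNS against ileum the TH17 core list had an estimated correlation of −0.0698, below the preset, yet camera p rose from 2.06e-25 to 0.00802. In all, 27 lists holding 464 genes were fixed, and 26 had the 3 tested members that were required. The choice of groups, tests, lists, alternatives and the naming rule was made before the data were examined, except where stated.

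Genes are named by a fixed rule. It takes Mir21a, Vmp1, Peli1 and Rel in every comparison. It adds the 8 largest positive and 8 largest negative log2 fold changes among called genes with a mean of at least 5 CPM, no overlap between the groups' libraries, and no predicted, clone, immunoglobulin or T cell receptor name. It adds up to 4 called members of each list, by smallest p, and the 5 genes of smallest p where none is called. Genes chosen after their values were seen are Csf2, Ccl4 and the sex-linked genes for CNS against ileum, Pfkm, Aldoc, Irf1, Ccr6 and Il2 for Ad-c-Rel, and Il17a, Il17f, Il22, Il23r, Irf4, Ccr2, Pdcd4, Cdc25a, Hk2, Pfkl, Slc2a1, Slc2a3 and Eno2 for the miR-21 knockout. Gapdh and Hk2 for CNS against ileum also fall outside the rule, and the counts of named genes leave them out.

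Called genes of one comparison, up to 200 by smallest p, were tested as sets in another with camera, and overlaps of calls with Fisher's exact test. No control library was shared between comparisons. Alternatives were DESeq2 1.42.0, relative log expression and upper quartile factors, no low-count filter, a filter of 5 CPM in 2 libraries, one fit over all 12 libraries, the replicate number as a block, a test against a 1.5-fold change, sets of up to 500 genes, and leaving out each library. A scaling to the T cell identity genes was added after seeing the data. A planned test of miR-21 seed matches was not run, because it needs transcript sequences that were not used here.

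The tests were tried on simulated counts drawn with the real means, spreads and library sizes, with 200 genes changed. The changed genes were drawn only from genes above a minimum mean count, so the recovered shares do not cover genes with fewer counts. More genes than 200 were called in the data for CNS against ileum (1163) and Ad-c-Rel (1673), so the adjustment acts differently there. For CNS against ileum (11306 genes), 0% of changes of 1.5-fold, 4.48% of 2-fold and 36.4% of 4-fold were recovered, with 5 false calls (15.6% of calls). For Ad-c-Rel (11590 genes) the shares were 76.1%, 94.0% and 100%, with 5 false calls. For the miR-21 knockout (13244 genes) they were 2.99%, 55.2% and 93.9%, with 6 false calls.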

Results

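RNA-seq counts were compared between 3 pairs of groups of mouse TH17 cells, each with 2 libraries per group. The title of the series names a pathway from miR-21 through Peli1, a ubiquitin ligase, to the NF-κB subunit c-Rel (gene Rel), and links it to glycolysis. RNA counts measure the Peli1 and Rel transcripts and not the level of their proteins. The comparisons ask how TH17 cells infiltrating the CNS differ from those of the ileum, what added c-Rel changes in TH17(β) cells, and what loss of miR-21 changes in pathogenic TH17 cells. Depth was 1.54e+07 to 1.99e+07 gene counts in the first 8 libraries and 3.28e+07 to 3.67e+07 in the 4 miR-21 libraries. Each comparison tested 26 gene lists.

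TH17 cytokine and receptor transcripts were far lower in the sorted CNS libraries than in the ileum libraries. The values describe whole sorted samples, which also held transcripts of other cell types. Il17a, the signature cytokine, was at 74.3 ± 0.646 CPM in CNS against 2591 ± 185 CPM in ileum (log2 fold change −5.12, SE 0.131, adjusted p = 0.000162 by edgeR). Il17f fell further, with a log2 fold change of −7.37 (SE 0.130), and Il22, a cytokine that acts on epithelium, reached −4.86 (SE 0.152). The receptor gene Il23r (−4.67, SE 0.340) and Rora, a lineage transcription factor (−2.59, SE 0.123), were lower too. In the TH17 core list, 9 of 14 tested genes were lower and 0 higher, or 10 lower when adjusted over the list alone (camera adjusted p = 2.67e-24). The list's adjusted p = 0.118 with an estimated correlation. Myeloid markers moved with tissue in the same libraries, with Lyz2 at 5283 CPM in CNS against 690 CPM in ileum.

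Chemokine and cytokine transcripts on the pathogenic TH17 list moved both ways. Ccl3 and Ccl4, chemokines that attract leukocytes, were higher in CNS by log2 fold changes of 3.01 (SE 0.151) and 2.60 (SE 0.172), and Csf2, which encodes GM-CSF, by 2.54 (SE 0.474, adjusted p = 0.0321). Myeloid markers were higher in the same libraries by a similar amount, with Lyz2 at 2.94 and C1qa at 2.57. Cxcl3 (−6.24, SE 0.325), Il22, Il23r and Icos (−2.10) were among 6 lower genes of 16 tested, against 4 higher, the same counts as when adjusted over the list alone. The list's median was −0.04 and its mean −0.92 (camera adjusted p = 9.21e-05, lower). Its adjusted p = 0.240 with an estimated correlation, and leaving out any 1 library ended the call (adjusted p 0.0607 to 0.412). The Csf2 call ended without CNS replicate 1 (adjusted p = 0.114) or CNS replicate 2 (adjusted p = 0.141). On the non-pathogenic TH17 list, 4 of 6 genes were lower, also over the list alone: Il10 (−4.01), Ikzf3 (−3.82), Ahr (−2.62) and Maf (−2.28). Camera gave adjusted p = 1.22e-10, and adjusted p = 0.177 with an estimated correlation.

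**Figure D1:**
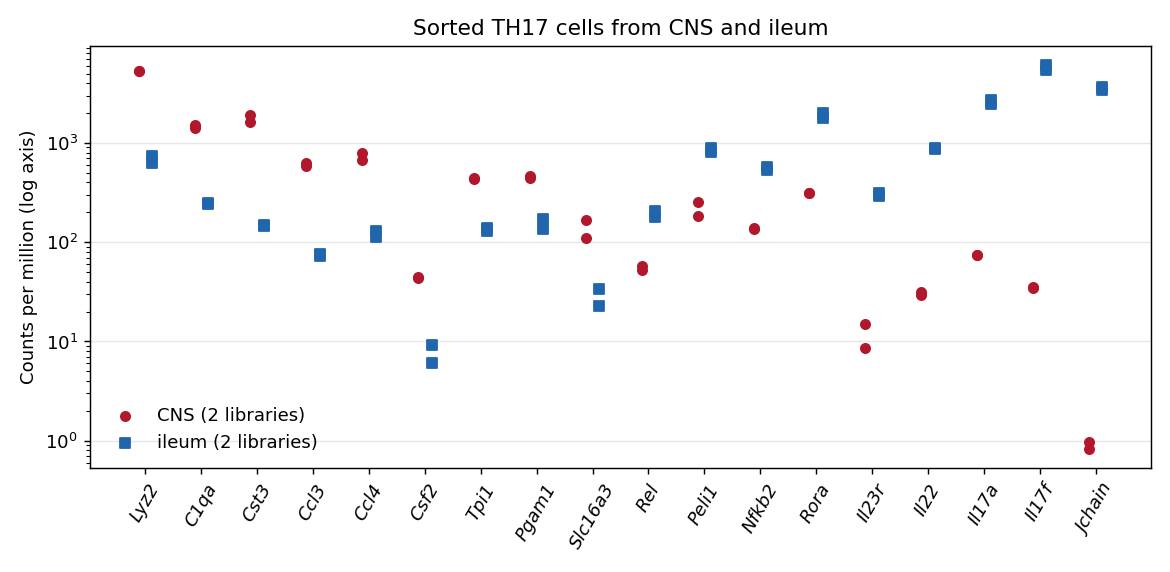
TMM-scaled CPM (log axis) of 18 genes in the 2 CNS libraries (red circles) and the 2 ileum libraries (blue squares), one point per library. Lyz2 averaged 5283 CPM in CNS against 690 CPM in ileum, and Il17a averaged 74.3 CPM against 2591 CPM.

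NF-κB genes were mostly lower in CNS. Rel was at 55.4 ± 3.75 CPM against 192 ± 20.1 CPM (log2 fold change −1.79, SE 0.207, adjusted p = 0.0081), and Nfkb2 (−2.01), Birc3 (−1.93) and Cd83 (−2.23) were lower with it. Tnf went the other way (2.91, SE 0.292). The list's median was −0.998, beside medians of −0.53 for T cell identity genes and 2.83 for myeloid markers in the same comparison. Over the list, 15 of 26 genes were lower and 3 higher, or 18 lower and 4 higher over the list alone (camera adjusted p = 8.79e-07, and adjusted p = 0.253 with an estimated correlation). Peli1 was at 219 ± 53.0 CPM against 849 ± 50.4 CPM (−1.95, SE 0.204, adjusted p = 0.00579). Mir21a had 29 counts in the CNS libraries and 32 in the ileum libraries and was not called (adjusted p = 0.938). Vmp1 was not called either (0.13, SE 0.225, adjusted p = 0.802).

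Genes of glucose uptake and glycolysis were higher in CNS in 7 of 22 tested members and lower in 0, or 9 higher and 2 lower over the list alone (median log2 fold change 0.67, camera adjusted p = 0.00173, and adjusted p = 0.278 with an estimated correlation). The enzymes Tpi1 (1.69, SE 0.148) and Pgam1 (1.57, SE 0.173), the lactate exporter Slc16a3 (2.29, SE 0.351) and Pgk1 (1.09, SE 0.172) led the list. The list's mean of 0.64 was 0.29 without CNS replicate 1 and 1.06 without ileum replicate 1. The Pgk1 call ended without ileum replicate 2 (adjusted p = 0.0593). Gapdh (−0.05) and Hk2 (−0.10) were not called. The median of the myeloid markers was 2.83 in the same comparison. On the hypoxia response list, which holds HIF-1 targets outside glycolysis and Hif1a itself, 2 genes were higher and 4 lower of 19. Bnip3, a HIF-1 target, was at 3.35, and the lower genes included Ndrg1 (−2.09), Hif1a (−0.94) and Rora, which is also on the TH17 core list. The Hif1a call ended when scaled to the T cell identity genes (adjusted p = 0.135). Camera did not call the list (adjusted p = 0.345, median 0.14, mean −0.10), and the mean was −0.87 without CNS replicate 1 and 1.29 without ileum replicate 1. No oxidative phosphorylation gene (26 tested) or TCA cycle gene (15 tested) was called.

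Transcripts of other cell types differed strongly between the tissues in the sorted samples. In CNS, 21 of 22 myeloid and microglia markers were higher, also over the list alone, with Lyz2 at 5283 ± 58.7 CPM against 690 ± 79.2 CPM and C1qa at 1465 ± 89.5 CPM against 246 ± 5.38 CPM (camera adjusted p = 2.41e-59, and adjusted p = 0.118 with an estimated correlation). Tmem119, a microglia gene, had 3 counts in the ileum libraries, a CNS to ileum ratio of 3894 with a counting interval of 1332 to 18884. In ileum, Jchain, the joining chain of secreted antibodies, was at 3538 ± 124 CPM against 0.903 ± 0.112 CPM. The B cell gene Ms4a1 had 0 counts in CNS and was at least 425-fold lower there, against a floor of 3 counts over the group. In all, 5 of 13 B and plasma cell markers were lower and 0 higher, or 7 lower over the list alone (camera adjusted p = 3.25e-14, and adjusted p = 0.240 with an estimated correlation). On the T cell identity list, 4 of 12 genes were lower, or 8 lower and 1 higher over the list alone, with a median of −0.53. Cd28 (−1.04) and Zap70 (−0.97) were among the lower genes (camera adjusted p = 0.00639, and adjusted p = 0.253 with an estimated correlation). These 2 calls ended when scaled to the list itself (adjusted p = 0.0903 and 0.0836).

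Under the rule for named genes, the largest differences included these. C4b, a complement gene, had 0 counts in ileum and was at least 2375-fold higher in CNS. F10, Ngp, Tspan7, Lrrc3 and Sort1 were at least 300-fold to 634-fold higher by the same floor, and Siglech, with 1 ileum count, had a ratio of 4586 with an interval of 823 to 181153. In the other direction Adamdec1 was at least 1822-fold lower in CNS, and C6, Glyat and Fam167a at least 253-fold to 488-fold lower. Xist, expressed from the inactive X chromosome, was at 0.0795 CPM in CNS against 412 CPM in ileum. The Y-linked gene Ddx3y was at 116 ± 5.61 CPM against 6.53 ± 5.56 CPM. Another Y-linked gene, Uty, did not separate the tissues, at 30.4 and 8.74 CPM in the CNS libraries and 3.26 and 9.04 CPM in the ileum libraries before TMM scaling.

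In all, 12038 genes were tested, of which 482 were higher and 681 lower in CNS, and 1035 of these differed at least 2-fold. DESeq2 called 1210 higher and 1330 lower, and scaling to the T cell identity genes, chosen after seeing the data, called 1014 and 362. Without ileum replicate 1 the higher genes numbered 1285, and without CNS replicate 2 they numbered 319.

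With c-Rel added to TH17(β) cells, most genes of the NF-κB and TH17 core lists were higher and most of the cell cycle list were lower. Rel itself was at 61.0 ± 3.51 CPM with Ad-c-Rel against 8.73 ± 2.49 CPM (7.07-fold, log2 fold change 2.82, SE 0.145, adjusted p = 6.91e-09). These counts do not separate the added from the endogenous transcript. Of 25 NF-κB genes, a list that includes the added Rel, 21 were higher and 1 lower, the same counts over the list alone (camera adjusted p = 4.72e-33, and adjusted p = 0.119 with an estimated correlation). Among them were Tnf (1.70, SE 0.150), the inhibitors Nfkbia (0.92, SE 0.0727) and Nfkbib (0.94, SE 0.0781), and Il2, the T cell growth factor, at 6.93 ± 0.794 CPM against 0.636 ± 0.367 CPM (3.37, SE 0.313). The lower gene was Irf1 (−0.44, adjusted p = 0.00483), whose call ended without Ad-control replicate 1 (adjusted p = 0.0650). Peli1 was not called (0.13, SE 0.0925, adjusted p = 0.371). Vmp1 passed narrowly (0.24, adjusted p = 0.0484) and lost its call without Ad-control replicate 1 and without either Ad-c-Rel library (adjusted p 0.128 to 0.297). Mir21a had 6 counts against 5 and was not tested.

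TH17 genes rose together with Ad-c-Rel. Il17f was at 6159 ± 29.1 CPM against 3153 ± 230 CPM (log2 fold change 0.97, SE 0.0788), Il17a at 277 ± 2.82 CPM against 146 ± 3.44 CPM (0.92, SE 0.0735) and Il21 at 1195 ± 47.4 CPM against 671 ± 60.9 CPM (0.83, SE 0.0809). The chemokine Ccl20 (1.94) and its receptor Ccr6 (1.09) were higher too. In the TH17 core list 9 of 14 genes were higher and 0 lower, or 10 higher over the list alone (camera adjusted p = 1.68e-18, and adjusted p = 0.119 with an estimated correlation). On the pathogenic TH17 list 10 of 16 were higher, or 11 over the list alone, including Ccl3 (2.86, SE 0.299), Ccl4 (2.57, SE 0.111) and Csf2 (2.19, SE 0.213). Camera gave adjusted p = 7.00e-16, and adjusted p = 0.124 with an estimated correlation. Il10 of the non-pathogenic list rose as well (0.76, SE 0.107). That list had 2 of 6 genes higher and was not called (adjusted p = 0.357).

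With Ad-c-Rel, 7 of 22 glycolysis genes were higher and 2 lower, the same counts over the list alone, and camera did not call the list (adjusted p = 0.0865). Among the higher genes were the glucose transporters Slc2a1 (0.36, SE 0.0726, adjusted p = 0.00379) and Slc2a3 (0.43, SE 0.0885) and hexokinase Hk2 (0.55, SE 0.0989). The lactate transporter Slc16a1 (0.35, SE 0.0819) was higher as well, but its call ended without Ad-control replicate 1 (adjusted p = 0.0687) or Ad-c-Rel replicate 2 (adjusted p = 0.0877). Pfkm (−0.36) and Aldoc (−0.25) were lower. The Pfkm call ended without Ad-control replicate 1 or Ad-c-Rel replicate 2 (adjusted p = 0.140 in both), and the Aldoc call without Ad-control replicate 2 or either Ad-c-Rel library (adjusted p 0.0687 to 0.207). On the hypoxia response list 12 of 20 were higher and 1 lower, or 13 higher over the list alone, with Ero1l (0.68), Ankrd37 (0.80) and Rora (0.59) as examples (camera adjusted p = 1.62e-07, and adjusted p = 0.124 with an estimated correlation).

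Cell cycle genes fell with Ad-c-Rel. Of 21 tested, 17 were lower and 0 higher, or 18 lower over the list alone (camera adjusted p = 4.28e-34, and adjusted p = 0.119 with an estimated correlation). The cyclins Ccnb2 (−1.62, SE 0.104) and Ccna2 (−1.55, SE 0.0968) and the mitotic regulator Cdc20 (−1.36, SE 0.0902) led the fall, and Pif1, Mtfr2, Troap, Nek2, Foxm1 and Cit were among the largest decreases under the rule for named genes (−1.56 to −2.17). Among 15 immediate early genes 10 were higher and 0 lower, or 11 higher over the list alone, including Nr4a1 (1.77), Hspa1b (2.20) and Egr1 (1.06) (camera adjusted p = 4.86e-21, and adjusted p = 0.119 with an estimated correlation). The largest increases under that rule, besides Rel, were Mcpt8 (4.56), Ccl4, Inhba (2.24), Pdzk1ip1 (2.22), Hspa1b, Csf2 and Ccdc184 (2.09). In all, 956 genes were higher and 717 lower of 11711 tested, with 293 changing at least 2-fold. DESeq2 called 636 and 431, and one fit over all 12 libraries, where the spread is pooled with more variable groups, called 18 and 1. Without Ad-c-Rel replicate 2 the counts were 537 and 389, and without Ad-control replicate 1 they were 541 and 394.

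In the miR-21 knockout libraries, Mir21a had 0 counts in both replicates against 25 and 20 in the controls, which is at least 13.3-fold lower against a floor of 3 counts over the group. The reads outside annotated genes made up 22.0% and 24.1% of the knockout tables and 20.4% and 18.8% of the control tables. No gene passed the threshold in the main fit: edgeR called 0 of 13428 genes (smallest adjusted p = 0.0625). At an unadjusted p under 0.05 there were 2821, 1289 higher and 1532 lower. With the replicate number as a block, edgeR called 2287 higher and 2520 lower. Deviations of same-numbered libraries from their group means correlated at 0.563. In groups of 2 the deviations of replicate 2 mirror those of replicate 1, so both pairs give the same value. The labels do not say that numbers mark shared animals or days. DESeq2 called 334 higher and 469 lower, and leaving out knockout replicate 1 gave 666 higher and 661 lower by edgeR. The 5 genes of smallest p were Atp6v0e2 (−5.59, SE 0.340), Ubb (1.66, SE 0.148), Myh11 (−2.08, SE 0.182), Ifitm1 (−1.61, SE 0.148) and Alpk2 (−1.36, SE 0.123), with adjusted p of 0.0625 for the first and 0.0938 for the others. Vmp1 was at 195 ± 6.22 CPM in the knockout against 114 ± 14.9 CPM (0.77, adjusted p = 0.125). Peli1 was at 227 ± 18.1 CPM against 165 ± 14.1 CPM (0.46, adjusted p = 0.173) and Rel at 64.8 ± 10.8 CPM against 42.8 ± 5.47 CPM (0.60, adjusted p = 0.161), neither past the threshold. Without knockout replicate 1, Vmp1 (adjusted p = 0.0364) and Rel (adjusted p = 0.0400) passed and Peli1 did not.

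**Figure D2:**
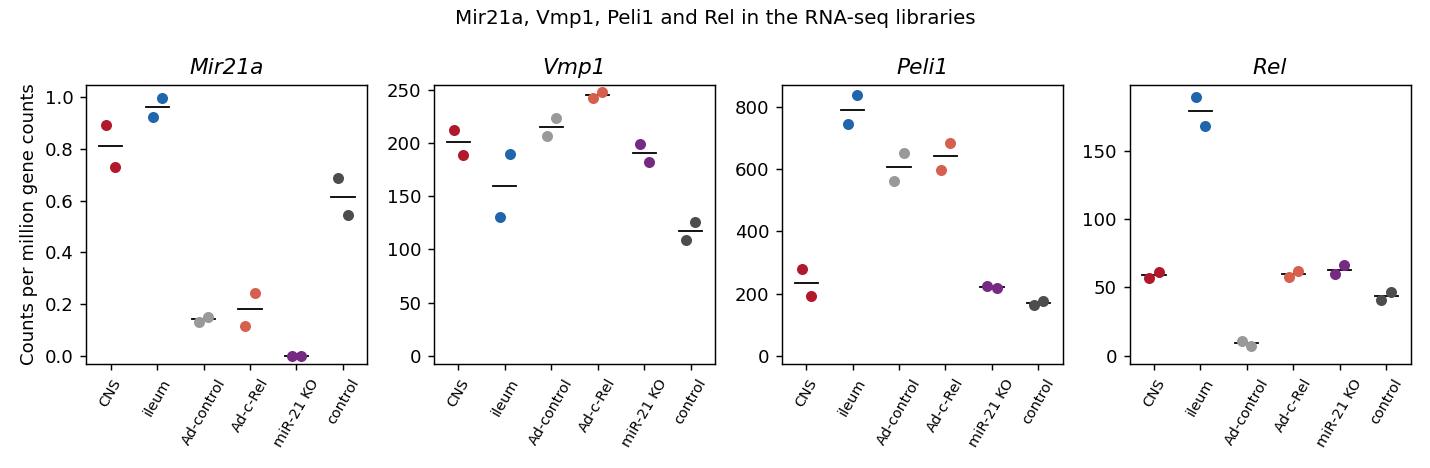
Mir21a, Vmp1, Peli1 and Rel in the 12 RNA-seq libraries, in CPM of gene counts with no TMM scaling. Each point is a library and each bar is the mean of 2. Mir21a is at 0 in both knockout libraries.

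TH17 core genes were lower in the knockout as a group by camera at the preset correlation, with no single gene called by edgeR in the main fit. DESeq2 called 15 of the 22 genes named for this comparison, among them Il17f, Il23r, Irf4 and Ccr2 but not Il17a or Il22. Il17a was at 61.9 ± 57.3 CPM against 331 ± 154 CPM (−2.42, SE 0.741, adjusted p = 0.172) and Il17f at 182 ± 142 CPM against 1056 ± 192 CPM (−2.54, SE 0.575, adjusted p = 0.135). Il23r (−1.08, adjusted p = 0.125), Irf4 (−0.98, adjusted p = 0.140) and the chemokine receptor Ccr2 (−1.45, adjusted p = 0.125) had lower means too. All 13 tested TH17 core genes had fitted changes below 0, and 5 were lower when adjusted over the list alone (median −0.54, camera adjusted p = 0.000429, and adjusted p = 0.717 with an estimated correlation). The pathogenic TH17 list had 14 of 17 below 0 (camera adjusted p = 0.0232, and adjusted p = 0.717 with an estimated correlation), with Il22 at −2.04 (SE 0.931). Without knockout replicate 1, Il17a was at −3.95 (adjusted p = 0.0105), Il17f at −3.70 (0.00458) and Il22 at −4.32 (0.00856), while Il22 was at −1.17 without knockout replicate 2, and without control replicate 1 Il17f reached 0.0242.

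Listed miR-21 targets were higher in the knockout as a group, with 13 of 18 above 0 and 3 higher over the list alone (camera adjusted p = 0.0164, and adjusted p = 0.717 with an estimated correlation). Cdc25a (1.15, adjusted p = 0.107) and the tumour suppressor Pdcd4 (0.77, adjusted p = 0.135) had the largest fitted increases there. The call ended without knockout replicate 1 (adjusted p = 0.0657). Glycolysis genes had 16 of 22 changes below 0 (median −0.26), 2 lower over the list alone by edgeR, and camera did not call the list (adjusted p = 0.0706). Examples were Hk2 (−0.84, adjusted p = 0.129), Pfkl (−0.77, adjusted p = 0.125), Slc2a3 (−0.76, adjusted p = 0.276) and Slc2a1 (−0.53, adjusted p = 0.468), while Eno2 was at 0.81 (adjusted p = 0.172). Of these, DESeq2 called Hk2, Pfkl and Eno2. The glycolysis list's mean log2 fold change of −0.19 was −0.39 without knockout replicate 2 and −0.32 without control replicate 1. It was −0.00401 without knockout replicate 1 and −0.0346 without control replicate 2. All 32 ribosomal protein genes had fitted changes above 0 (median 0.40, mean 0.40 and 0.22 without knockout replicate 2, camera adjusted p = 5.60e-07, and adjusted p = 0.717 with an estimated correlation).

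**Figure D3:**
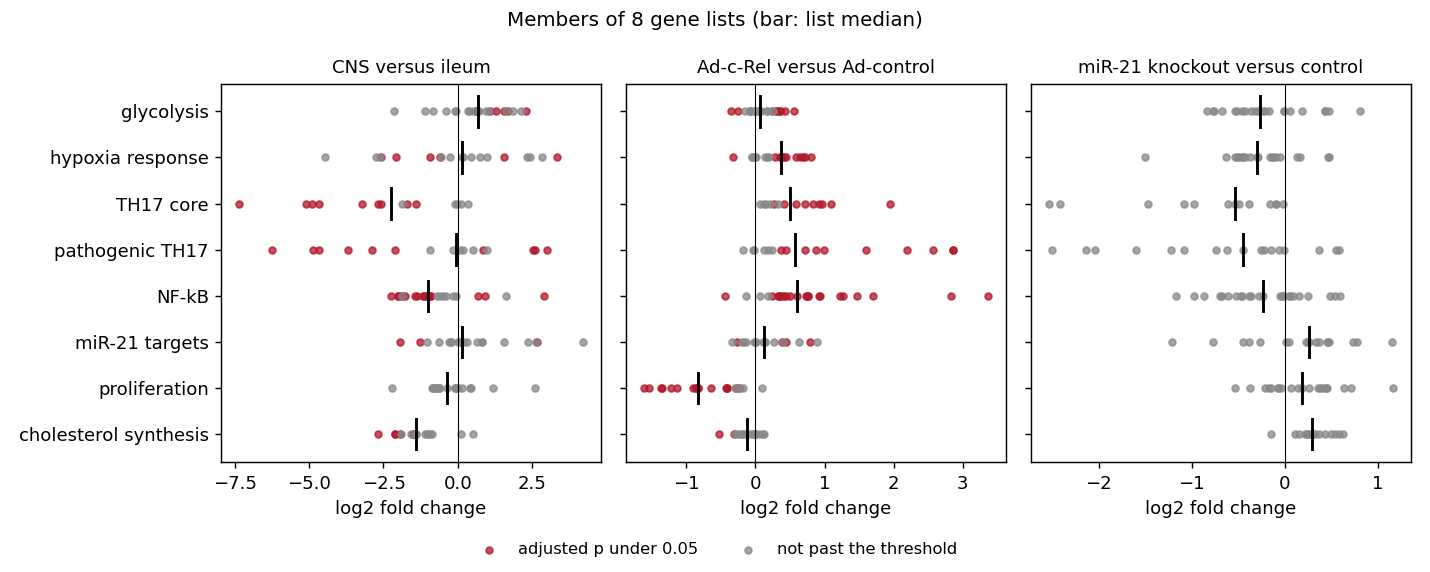
Log2 fold changes of the tested members of 8 gene lists in the 3 comparisons, with one point per gene, red where the edgeR adjusted p is under 0.05 and grey otherwise. Black bars are list medians, and each panel has its own scale. The TH17 core median is −2.24 in CNS against ileum, 0.51 with Ad-c-Rel and −0.54 in the miR-21 knockout.

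Genes called in one comparison were then followed in the others, in 6 set tests. Of 657 genes lower in CNS that were also tested with Ad-c-Rel, 188 rose with Ad-c-Rel, against 53.2 by chance overlap of independent lists (Fisher's exact test, two-sided p = 4.05e-59). Among 372 genes higher in CNS, 60 rose with Ad-c-Rel against 30.1 by chance (p = 1.89e-07, Fisher's exact test). Of the genes lower in CNS, 17 fell with Ad-c-Rel against 42.0 by chance (p = 7.33e-06, Fisher's exact test). Of those higher in CNS, 28 fell against 23.8 (p = 0.387, Fisher's exact test). Fisher's test counts genes as independent draws, so these p-values do not measure the spread between libraries. The 200 genes of smallest p higher in CNS had a mean log2 fold change of 0.23 with Ad-c-Rel (camera adjusted p = 0.0124, and adjusted p = 0.237 with an estimated correlation). The 200 lower in CNS had a mean log2 fold change of 0.34 with Ad-c-Rel, and 82 were called higher (camera adjusted p = 1.42e-25, and adjusted p = 0.0681 with an estimated correlation). The 200 genes of smallest p raised by Ad-c-Rel had a mean of −0.32 in the miR-21 knockout, with 147 below 0 (camera adjusted p = 2.65e-06, and adjusted p = 0.237 with an estimated correlation). The 200 lowered by Ad-c-Rel had a mean of 0.37 there, with 165 above 0 (camera adjusted p = 6.72e-13, and adjusted p = 0.441 with an estimated correlation). The first mean was −0.49 without knockout replicate 1, and the second 0.22 without knockout replicate 2. Across 11614 genes the fold changes of the Ad-c-Rel and knockout comparisons had a Pearson r of −0.19, a description only, since genes are not independent replicates. The CNS-ileum sets were not called in the knockout (camera adjusted p = 0.171 for both).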

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

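One signal lay outside the gene counts. The share of reads that fell in no annotated gene was 22.0% and 24.1% in the miR-21 knockout libraries and 20.4% and 18.8% in their controls, so that both knockout libraries lay above both controls. With 2 libraries per group this ordering has a chance of 33.3% over both directions, and it was not tested further.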

How the results depend on the processing

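Higher and lower counts for CNS against ileum were 482 and 681 in the main analysis, 1210 and 1330 by DESeq2, 1113 and 1300 with no low-count filter, 1988 and 2012 in one fit over all 12 libraries, and 315 and 401 against a 1.5-fold change. Scaling to the T cell identity genes, chosen after seeing the data, shifted log2 fold changes by a median of 0.50 and gave 1014 and 362, so that 73.7% of calls were higher against 41.4%. For Ad-c-Rel the counts were 956 and 717, then 636 and 431 by DESeq2, 18 and 1 in one fit over all 12 libraries, where the spread is pooled with more variable groups, and 131 and 81 against a 1.5-fold change. For the miR-21 knockout the counts were 0 and 0, then 334 and 469 by DESeq2, 9 and 31 with no low-count filter, and 0 and 1 in the fit over all 12 libraries. With the replicate number as a replicate block, Ad-c-Rel gave 1488 and 1314, the knockout 2287 and 2520, with all 22 named genes past the threshold, and CNS against ileum 534 and 775. Deviations of same-numbered libraries correlated at 0.108 for CNS and ileum, 0.0435 for Ad-c-Rel and 0.563 for the knockout. In groups of 2 both pairs give the same value, and the labels do not say that numbers mark shared animals or days. Leaving out single libraries gave 319 to 1285 higher and 531 to 724 lower for CNS against ileum, 537 to 784 and 389 to 597 for Ad-c-Rel, and 1 to 666 and 1 to 661 for the knockout. The group left with a lone library is assumed to vary like the other. Lists passing were 15, 11 and 9 in the 3 comparisons. They were 0 in each with an estimated correlation, a form with only 2 residual degrees of freedom. In the knockout they were 14 with the block, 0 by fry and 9 to 15 without single libraries. The glycolysis mean was 0.64 in CNS against ileum, 0.29 to 1.06 without single libraries (adjusted p = 0.278 with an estimated correlation), 0.10 with Ad-c-Rel (adjusted p = 0.0366 by fry, and −0.00785 with adjusted p = 0.129 with no low-count filter) and −0.19 in the knockout. There it was −0.35 with no low-count filter (adjusted p = 0.0362), −0.21 with the block (adjusted p = 0.0264) and −0.39 to −0.00401 without single libraries. Genes higher in CNS had a mean of 0.23 with Ad-c-Rel (adjusted p = 0.237 with an estimated correlation) and 0.15 in sets of up to 500 genes (adjusted p = 0.0729). Genes lower in CNS had 0.34 there (adjusted p = 0.0681 with an estimated correlation). Without single libraries, genes higher in CNS had −0.18 to −0.0675 in the knockout and genes lower in CNS −0.17 to −0.0642, with smallest adjusted p of 0.0267 and 0.00991. Genes raised and lowered by Ad-c-Rel had −0.32 and 0.37 in the knockout (adjusted p = 0.237 and 0.441 with an estimated correlation), and −0.49 to −0.25 and 0.22 to 0.51 without single libraries. Among single genes, signs turned for Vmp1 in CNS against ileum (0.13 in the main analysis, −0.0934 to 0.40 without single libraries), for Mir21a (−0.44 in the main analysis, 0.0471 with T cell scaling) neither of them past the threshold. List means turned sign under at least 1 setting for 12, 5 and 8 of the 26 lists in the 3 comparisons, of which 3 passed in the main analysis, in CNS against ileum. These are ribosomal proteins (−0.26, and 0.23 with T cell scaling), TH1 and cytotoxic genes (−0.87, and 0.85 without ileum replicate 1) and homing (−0.30, and 0.10 without ileum replicate 1). Of the 87 genes named for CNS against ileum 85 were called, and 73 of the 87 kept direction and side of the threshold under all settings but the T cell scaling. That scaling ended 9 calls, of Rplp0, Cd247, Skil, Hif1a, Zap70, Atf4, Cd28, Fasl and Insig1 (adjusted p 0.0704 to 0.659). Of 88 named for Ad-c-Rel 87 were called and 7 of the 88 kept both, while 81 lost the call in the fit over all 12 libraries. The cause was not tested for any of these shifts, except that the T cell scaling moves every gene by its own construction. Depth limits Mir21a, with 0 to 25 counts per library. The planned seed-match test for miR-21 was not run, for want of transcript sequences.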

Other observations

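The tests with a stated explanation below, and the scaling to T cell identity genes, were chosen after the results were seen. The other gene lists add to the picture. In CNS against ileum, 6 of 22 interferon response genes were higher and 0 lower, or 8 higher over the list alone, including Gbp2 (log2 fold change 3.16) and Irgm1 (1.89) (camera adjusted p = 2.76e-06, and adjusted p = 0.253 with an estimated correlation). Myeloid markers, with a median of 2.83, were higher in the same CNS libraries. Cholesterol synthesis genes were lower in CNS in 6 of 17, or 9 over the list alone, with Cyp51 (−2.69) and Sqle (−2.11) as examples (camera adjusted p = 2.24e-05, and adjusted p = 0.253 with an estimated correlation). Of 19 homing and residency genes 6 were lower and 1 higher, or 8 lower and 6 higher over the list alone. The lower genes included the gut-homing receptor Ccr9 at −4.39 and Rgs1 at −3.11 (list median 0.06, mean −0.30, camera adjusted p = 0.00339, and adjusted p = 0.256 with an estimated correlation). The homing call ended without any 1 library (adjusted p 0.141 to 0.264) and with the T cell scaling (mean 0.20, adjusted p = 0.0772). TH1 and cytotoxic genes were lower in 5 of 14 and higher in 1, with Gzma at −7.20 and Gzmb at −3.70 (camera adjusted p = 0.0012, and adjusted p = 0.253 with an estimated correlation), and that call ended without any 1 library as well (adjusted p 0.104 to 0.469, mean −1.14 to 0.85). Treg and TGF-β genes were lower in 4 of 13 and higher in 1, with Ctla4 at −3.82 (camera adjusted p = 0.00468, and adjusted p = 0.437 with an estimated correlation). The Treg call ended without CNS replicate 2 (adjusted p = 0.0503). Of 7 neural and glial markers 2 were higher, Apoe (1.98) and Slc1a3 (7.58) (camera adjusted p = 0.00689, and adjusted p = 0.253 with an estimated correlation). Both are also expressed by other cells, and the Slc1a3 call ended without CNS replicate 1 (adjusted p = 0.113) or CNS replicate 2 (adjusted p = 0.0931). Ribosomal protein genes had 30 of 32 changes below 0 with 1 called (camera adjusted p = 0.0247, and adjusted p = 0.773 with an estimated correlation), and their mean turned to 0.23 when scaled to the T cell identity genes. Immediate early genes went both ways, 6 higher and 5 lower of 16, with Ier3 at 3.49 and Hspa1a at −4.39 (camera adjusted p = 0.313, and 0.00739 with the T cell scaling). Camera called none of TH2 (adjusted p = 0.778), miR-21 targets (0.539), proliferation (0.307), the ATF4 list of amino acid and integrated stress response (0.702), epithelial markers (0.527), CD8 T, NK and gamma-delta markers (0.526) or stromal and endothelial markers (0.170).

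With Ad-c-Rel, TH2 genes were higher in 4 of 6, including Ccr8 (1.36) and Il24 (0.93) (camera adjusted p = 7.06e-07, and adjusted p = 0.124 with an estimated correlation). Treg and TGF-β genes were higher in 5 of 13, with Ctla4 at 0.83 (camera adjusted p = 0.000983, and adjusted p = 0.443 with an estimated correlation). TH1 and cytotoxic genes were higher in 3 of 13 and lower in 1, with Nkg7 at 1.41 (camera adjusted p = 0.00387, and adjusted p = 0.250 with an estimated correlation). Within the proliferation list, a split chosen after the values were seen gave a mean of −1.14 for 11 mitotic genes and −0.30 for 10 S-phase genes. Klf2, a quiescence and recirculation factor, was lower (−1.33). Myeloid markers were higher in 3 of 8 at low levels, with Tmem119 at 13.9 CPM against 5.02 CPM (camera adjusted p = 0.0278, and adjusted p = 0.444 with an estimated correlation). T cell identity genes were higher in 4 of 12 and lower in 1 (camera adjusted p = 0.0488, and adjusted p = 0.443 with an estimated correlation). Leaving out single libraries ended the myeloid call in 2 of 4 fits (largest adjusted p = 0.128, without Ad-c-Rel replicate 1) and the T cell call in 3 of 4 (largest adjusted p = 0.0969, without Ad-c-Rel replicate 2). Camera called none of oxidative phosphorylation (adjusted p = 0.803), TCA cycle (0.258), miR-21 targets (0.324), homing (0.401), interferon response (0.500), the ATF4 list (0.0619), cholesterol synthesis (0.0619), ribosomal proteins (0.658) or epithelial (0.525), B and plasma cell (0.168), neural (0.588), CD8 T and NK (0.500) and stromal markers (0.0605). In the miR-21 knockout, cholesterol synthesis genes had 16 of 17 changes above 0 (camera adjusted p = 0.00191), and TH1 and cytotoxic genes had 12 of 14 below 0 (0.00972), TH2 genes 6 of 8 (0.0388), homing genes 13 of 18 (0.0388) and stromal markers 4 of 6 (0.0179). With an estimated correlation each of these had adjusted p = 0.717. Leaving out knockout replicate 2 ended the TH2 call (adjusted p = 0.0944) and the homing call (0.0736), and leaving out knockout replicate 1 or control replicate 2 ended the stromal call (0.0657 and 0.0956). Camera called none of hypoxia response (0.0779), non-pathogenic TH17 (0.0754), oxidative phosphorylation (0.376), TCA cycle (0.529), Treg (0.256), NF-κB (0.113), interferon response (0.140), immediate early (0.655), proliferation (0.113), the ATF4 list (0.155) or epithelial (0.274), myeloid (0.659), B and plasma cell (0.376), neural (0.893), CD8 T and NK (0.376) and T cell identity (0.376) genes.

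Myeloid and microglia markers were higher in CNS libraries in 21 of 22 tested members, in samples that were sorted as GFP-positive. That count restates the pattern, so whether RNA of other cells or the TH17 cells themselves gave these transcripts cannot be told apart. A lower share of T cells alone would raise the markers of every other type, whereas the B and plasma cell list had a median of −5.58 in CNS. Ileum libraries also held myeloid transcripts, with Lyz2 at 690 CPM.

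TH17 core genes were lower in CNS libraries in 9 of 14 members (list adjusted p = 0.118 with an estimated correlation), and dilution of T cell RNA by other cells was tested as the whole cause. After scaling to the T cell identity genes, 8 of the 9 TH17 core genes called lower were still called lower. The TH17 core median lay −1.71 from the T cell identity median. Both rest on the same gap between the 2 lists, so they count as a single argument. That gap argues against dilution by cells other than T cells as the whole cause. Dilution by T cells of another type would not lower the T cell identity genes, so the scaling cannot decide it. The sex of the mice cannot be told apart from tissue, because Xist was at 375 CPM or more in both ileum libraries and at most 0.119 CPM in CNS, so no library separates them. Of the Y-linked genes, Kdm5d was at 24.96 and 6.81 CPM in CNS and 0 in ileum and Eif2s3y at 115 and 140 CPM against 6.15 and 0, whereas Uty was at 30.4 and 8.74 CPM against 3.26 and 9.04. Tissue and disease state, which the design names, stay open and untested.

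Glycolysis genes were higher in CNS libraries in 7 of 22 members, with 6 fitted below 0 (list adjusted p = 0.278 with an estimated correlation). The list's lowest mean log2 fold change over 3 scalings was 0.64, but none of them lowered fold changes enough to bring it to 0, so the part played by scaling stays open. Whether the transcripts came from TH17 cells or from myeloid cells cannot be told apart. Both CNS libraries lay above both ileum libraries by at least 3.59 in mean log2 CPM of the myeloid list, so no library shows one change without the other.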
